A study of Homo sapiens with 6 samples.

How the data were processed

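Single-cell 3′ messenger RNA libraries of BJ fibroblasts under induced OCT4, SOX2, KLF4 and MYC were used, 1 library for each of 6 groups: day 0, day 2, day 8, day 12 and the TRA-1-60 negative and positive fractions of day 16. The deposited table holds raw UMI counts per Ensembl gene and cell, and a deposited text table gives the time point of each cell. The submitters' processing notes name Cell Ranger 2.1.0, the hg19 genome and Seurat. Their filters on cells were not stated. All values of the table were whole numbers of at least 0, 32738 features by 32138 cells, and every cell had a time point. Gene symbols came from a later annotation than the one used for counting, so no coordinates are given; 30860 features had a symbol, and 0.343% of UMIs fell on features without one. Genes of the Y chromosome and XIST, 133 features in all, were left out of every table.

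All cells were kept for the main values. UMIs were summed over the cells of each library and scaled to CPM of the library's sum. Library sums ran from 96332121 to 137060171 UMIs, so that 1 UMI stood for well under 1 CPM and the floor of 3 counts per library stood for 0.0219 CPM at day 0. The 6 comparisons were day 2 against day 0, day 8 against day 2, day 12 against day 8, the day 16 fractions against each other, and each fraction against day 0. Groups had 1 library each, so no test was made. A gene was counted as higher or lower when it had at least 25 CPM in the higher library and a ratio of at least 2. Ratios of named genes have exact conditional binomial 95% intervals, and a gene at 0 in 1 library was compared with the floor. Mitochondrially encoded genes (13) were left out of these counts.

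Genes were named by a fixed rule. For each comparison it took the 12 largest and 12 smallest ratios among genes with at least 50 CPM in the higher library, leaving out ribosomal protein, mitochondrial and clone-named genes. It added up to 4 members of each gene list with the largest log2 ratios among members with at least 25 CPM, and POU5F1, SOX2, KLF4, MYC, NANOG, LIN28A, PODXL and GAPDH. Only part of the genes so named are printed. For 29 gene lists the share of UMIs was taken with exact Clopper-Pearson 95% intervals, and for 28 the median log2 ratio of CPM plus 1 over members with at least 5 CPM in either library. Each median was set beside 10000 random lists of the same size drawn within 20 bins of mean expression. List members not found by symbol included ESRG, LHX1, PECAM1, UHRF1 and CASP8AP2. The comparisons, lists, rule of size, rule for naming and most alternatives were chosen before the data were examined.

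For shares of cells, every cell was thinned to 11000 UMIs, the 10th percentile of all cells rounded down to a multiple of 500, and shallower cells were left out. Day 0 served as background for pluripotency genes and the TRA-1-60 positive library for fibroblast genes. Clusters were found with scanpy 1.11.5 and leidenalg 0.10.2 at resolution 0.5, on 30 principal components of the 2000 most variable genes of log-normalised counts with 15 neighbours. No correction between libraries was made. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used throughout.

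Alternatives were TMM factors from edgeR 4.0.16 and median-of-ratios factors from DESeq2 1.42.0 under R 4.3.3, the mean over cells of each cell's CPM, and cells with at least 1000 genes and at most 10% mitochondrial UMIs. Further ones were cells without predicted doublets, other minimum levels and ratios, other pseudocounts and list minimums, other depths and settings of the clusters. Scrublet's automatic threshold marked at most 8 cells of a library. The calculations were tested on simulated data with planted ratios. All 50 genes planted at 3-fold in each direction were counted in each of the 6 comparisons, none planted at 1.5-fold were, and planted lists lay at the 100th percentile. Planted genes had at least 50 CPM and counting error only, so this checked the calculation and not the spread between cells or libraries. In a first small simulation of the thinning 1 of 2 checks lay over 2 standard errors from the planted share, and in a larger one 2 of 36, with a mean standardised gap of -0.01.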

Results

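Messenger RNA was counted in single cells of BJ, an established line of human neonatal foreskin fibroblasts, during reprogramming towards pluripotency. Virus-borne OCT4, SOX2, KLF4 and MYC were induced in the cells, and OCT4 is the product of POU5F1. Cells were taken at day 0, day 2, day 8, day 12 and day 16 of induction. The day 16 cells formed a fraction negative and a fraction positive for TRA-1-60, a sugar epitope on the surface protein podocalyxin (PODXL) that marks human pluripotent cells. Each of the 6 groups was 1 library, so there were no replicates and no difference could be set against a spread between replicates. The libraries held 7079 cells at day 0, 4988 at day 2, 3619 at day 8, 7013 at day 12, 6781 in the TRA-1-60 negative fraction and 2658 in the positive fraction.

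The library totals, in the same order, were 137060171, 125020298, 113577497, 121532308, 117673441 and 96332121 UMIs, that is, distinct transcript molecules. The median cell held 18449, 24012, 30040, 16017, 15714 and 33562 UMIs. Levels were expressed as CPM, the UMIs of a gene per 1000000 UMIs of the library. The bracketed range after a fold is its 95% counting interval. Such intervals cover counting error only. For named genes with at least 25 CPM in both libraries of a comparison the interval was at most 5.16% wide to either side of the fold. The bracketed range after a list's median log2 ratio is the middle 95% of random lists of similar expression. Counts of genes at least 2-fold higher or lower follow a rule of size, not a call of change.

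The key genes set the frame for the comparisons. POU5F1 (ENSG00000204531) was at 0.0219, 9.65, 10.1 and 42.2 CPM at days 0, 2, 8 and 12, then at 10.6 CPM in the TRA-1-60 negative and 1065 CPM in the positive library. NANOG (ENSG00000111704), a core pluripotency transcription factor, was at 0.0803, 0.216, 6.04, 17.7, 13.1 and 152 CPM in the same order. LIN28A (ENSG00000131914), an RNA-binding protein of pluripotent cells, had no UMI at day 0 or day 2, and was at 1.51, 18.7, 1.21 and 149 CPM afterwards. SOX2 (ENSG00000181449) had no UMI at day 0 and was at 10.9, 2.67, 5.25, 4.10 and 17.2 CPM. KLF4 (ENSG00000136826) was at 1.13, 7.01, 3.84, 4.32, 2.91 and 13.0 CPM. MYC (ENSG00000136997) was at 34.8, 53.6, 18.2, 26.0, 33.0 and 34.2 CPM. PODXL (ENSG00000128567) was at 4.49, 15.7, 131, 171, 161 and 203 CPM. GAPDH (ENSG00000111640), which encodes a glycolytic enzyme, was at 5372, 3332, 3111, 2435, 3059.7 and 2832 CPM. The counts do not separate virus-borne from endogenous transcripts of the 4 factors, and tags of POU5F1 and its near-identical retrocopy POU5F1B can be exchanged.

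**Figure D1:**
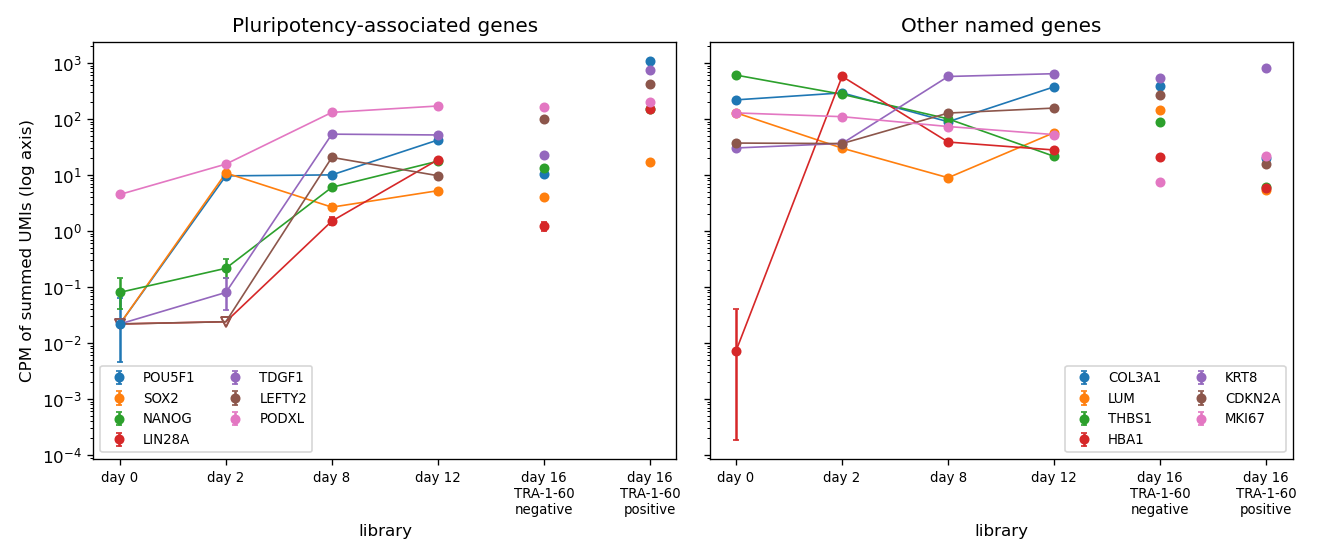
Level of selected genes in each library, in CPM on a log axis, against library, with bars for the 95% Poisson counting interval; open triangles mark 0 UMIs drawn at the floor of 3 counts, and lines join days 0 to 12 only. POU5F1 stands at 1065 CPM in the TRA-1-60 positive and 10.6 CPM in the negative library.

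Day 2 against day 0 asked which transcripts differed soonest after the factors were induced. At day 2 the cells had lower fibroblast matrix, contractile, TGF-beta-responsive and BMP-responsive transcripts. Transcripts that day 0 cells lacked, among them alpha-globin, KRT14, KRT6A and SOX2 transcripts, were present. Of the pluripotency genes a few were higher, and NANOG, LIN28A and TDGF1 were at or near 0 in both libraries. By the rule of size 192 genes were higher and 208 lower of 4675 genes with at least 25 CPM. This split depended on the scaling: it was 152 higher and 282 lower with TMM factors, 140 and 306 with median-of-ratios factors, and 320 and 196 when ribosomal protein and mitochondrial UMIs were left out of the total.

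The highest ratios belonged to genes nearly absent at day 0. HBA1 and HBA2, which encode alpha-globin, reached 577 and 518 CPM at day 2, against 1 and 0 UMIs at day 0; the copies are near identical, so the split between them is uncertain. HBZ, the embryonic zeta-globin, reached 173 CPM and the keratinocyte surface gene LY6D 191 CPM, each from 3 UMIs at day 0. The host transcript of the miR-302 cluster, MIR302CHG, which is tied to pluripotency, was at least 3729-fold higher, against a floor of 3 counts per library. Basal keratin KRT14 was 1276-fold (586 to 3479) higher, and KRT6A, a keratin of stratified epithelium, was at least 2344-fold higher. S100A2, also in the keratinocyte list, was 10.9-fold higher, and the median of that list's 5 measured members was 3.34 (random lists -0.52 to 0.64), or 7.95 with members at 0 set to the floor. NFATC2, a calcium-regulated transcription factor, was 422-fold higher, the growth factor IGF2 40.0-fold higher and the integrin regulator FERMT1 28.7-fold higher. SOX2 was at least 497-fold higher and KLF4 6.20-fold (5.22 to 7.40) higher, while POU5F1 reached 9.65 CPM from 3 UMIs. MYC was 1.54-fold (1.48 to 1.60) higher. In the pluripotency list POLR3G, a subunit of RNA polymerase III, was 3.50-fold higher and the tetraspanin CD9 2.24-fold higher, and the list's 6 measured members had a median of 1.43 (random lists -0.41 to 0.53), or 0.02 over all members with any UMI. UTF1 and L1TD1, named here after their values were seen, were at 0 and 2.1 CPM at day 0 and at 14.6 and 11.6 CPM at day 2, while TDGF1 was at 0.0800 CPM and NANOG at 0.216 CPM at day 2. The stress-responsive growth factor GDF15 was 5.67-fold higher, whereas GADD45B and TP53I3 of the same p53 target list were 3.91-fold and 2.48-fold lower.

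The helix-loop-helix inhibitors ID4, ID3 and ID2, which are direct BMP targets, were 7.20-fold, 4.63-fold (4.58 to 4.68) and 3.58-fold lower, and the BMP target list had a median of -1.36 (random lists -0.41 to 0.39). MSX1 was the exception in that list, 3.79-fold higher. Smooth muscle actin ACTA2 was 4.77-fold (4.66 to 4.88) lower, tropomyosin TPM1 3.67-fold lower and calponin CNN1 3.56-fold lower; 5 of 10 contractile genes were at least 2-fold lower, against 1 higher, the muscle filament gene DES. CCN1 and CCN2, targets of the YAP pathway, were 3.65-fold and 3.19-fold lower, and the list of TGF-beta and YAP targets had a median of -0.76 (random lists -0.30 to 0.35). In the fibroblast list the collagen-binding proteoglycan LUM was 4.28-fold lower, the mesenchymal transcription factor SNAI2 4.31-fold lower, the growth factor receptor PDGFRB 3.94-fold lower and CALD1 2.68-fold lower, with 8 of 27 members at least 2-fold lower, none higher and a median of -0.75 (random lists -0.15 to 0.19). CITED2, the oxytocin receptor OXTR, the matrix protein CTHRC1 and the methyltransferase NNMT were 5.87-fold, 4.66-fold, 4.68-fold and 4.62-fold lower. The secreted factors IGFBP3 and MMP3 were 3.59-fold and 3.01-fold lower, although IGFBP5 of the same list was 2.11-fold higher. Immediate early genes were mixed, with DUSP1 3.85-fold and JUN 2.95-fold lower and JUNB 2.5-fold higher. ATF4-pathway genes ASNS and DDIT3 were 2.46-fold and 2.17-fold lower, and the heat shock gene HSPE1 2.06-fold higher. The median of 15 unfolded protein and heat shock genes was -0.52 (random lists -0.26 to 0.27). Ribosomal protein genes made up 22.5% of UMIs at day 0 and 26.8% at day 2.

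Day 8 against day 2 asked what followed in the first week. Epithelial and early pluripotency transcripts were higher at day 8, the fibroblast matrix and contractile transcripts were lower again, and the mesenchymal surface list was lower as well. BMP targets were lower once more, and the globin transcripts of day 2 were much lower. Counted by size, 245 genes were higher and 303 lower of 4676, but 374 and 341 when ribosomal protein and mitochondrial UMIs were left out of the total. Among genes at least 4-fold apart the order with all UMIs was also the other way round, 113 higher and 59 lower.

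The Nodal co-receptor TDGF1, a marker of human pluripotent cells, was 671-fold (365 to 1399.5) higher at day 8 and reached 53.7 CPM. L1TD1, an RNA-binding protein of pluripotent cells, was 9.83-fold higher, NANOG 28.0-fold higher and ETV4 2.96-fold higher. LIN28A was at least 62.7-fold higher, at 1.51 CPM. The 12 measured pluripotency genes had a median of 1.87 (random lists -0.50 to 0.41), although POLR3G was 1.93-fold lower. ARGFX, a homeobox gene of the early embryo, was 7.15-fold higher and KLF5 4.67-fold higher. Demethylase TET1 was 6.11-fold higher. PODXL was 8.38-fold (8.00 to 8.79) higher. The epithelial list had a median of 2.31 (random lists -0.48 to 0.47): the protease inhibitor SPINT2 was 106-fold higher, the simple-epithelium keratins KRT8 and KRT19 were 15.7-fold and 5.93-fold higher, and desmoplakin (DSP) was 3.23-fold lower. The prostaglandin-degrading enzyme HPGD was at least 3857-fold higher, the homeobox gene HOXD1 1613-fold higher and the cornified-envelope gene SPRR3 791-fold higher. CD70, a ligand of the TNF family, was 304-fold higher, the secreted phosphoprotein SPP1 217-fold higher and the metallothionein MT1H 169.8-fold higher. HAND1, a transcription factor of mesoderm, trophoblast and amnion, was 25.1-fold higher. Cell cycle inhibitor CDKN2A was 3.51-fold (3.39 to 3.63) higher and the p53 target BBC3 2.32-fold higher, and the list of such genes had a median of 0.32 (random lists -0.41 to 0.08). Nuclear-encoded oxidative phosphorylation genes had a median of 0.37 (random lists -0.20 to 0.12), led by COX6C at 2.68-fold higher.

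HBA1 and HBA2 were 14.9-fold and 18.0-fold lower at day 8, and HBZ 9.32-fold lower. The BMP targets ID2, ID3 and ID1 were 10.9-fold, 9.31-fold and 7.04-fold lower, with 4 of 5 list members at least 2-fold lower and BAMBI 6.15-fold higher. In the fibroblast list the collagen COL1A1 was 7.07-fold (6.98 to 7.16) lower, fibronectin (FN1) 7.09-fold lower, THBS2 5.81-fold lower and COL6A2 4.92-fold lower; 14 of 25 members were at least 2-fold lower and none higher. Elastin (ELN), biglycan (BGN) and the pericyte and fibroblast receptor CD248 were 9.34-fold, 8.77-fold and 10.3-fold lower. Mesenchymal surface genes had a median of -0.86 (random lists -0.42 to 0.18), with CAV1 2.65-fold lower, the integrin ITGA5 2.54-fold lower, the aminopeptidase ANPEP 2.36-fold lower and endoglin (ENG) 2.35-fold lower. The actin-binding TAGLN was 3.51-fold lower and ACTA2 2.71-fold lower, whereas ACTG2 was 5.94-fold higher. The contractile list as a whole held 0.312% of UMIs at day 8, against 0.586% at day 2. The secreted IGFBP3 and the cytokine IL11 were 5.35-fold and 10.2-fold lower. YAP target ANKRD1 was 31.3-fold higher. JUNB was 5.06-fold lower. Of the induced factors SOX2 was 4.08-fold lower and MYC 2.95-fold lower. Ribonucleotide reductase RRM2 was 2.62-fold lower. The interferon list had a median of -0.52 (random lists -0.43 to 0.22) but was mixed, with IFI27 8.49-fold and MX1 4.17-fold higher.

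Day 12 against day 8 asked what differed in the second week, before the cells were parted by TRA-1-60. Fewer genes differed than in the earlier steps. Pluripotency and BMP-responsive transcripts were higher in the library's sum, and so were several matrix genes. The pluripotency transcripts were spread unevenly over the cells. Targets of YAP and TGF-beta were lower, with the proliferation transcripts slightly lower. By size, 129 genes were higher and 115 lower of 4361, and 272 and 95 when ribosomal protein and mitochondrial UMIs were left out of the total. Ribosomal protein genes made up 28.5% of UMIs at day 8 and 34.1% at day 12.

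LIN28A was 12.4-fold (10.7 to 14.6) higher at day 12, POU5F1 4.20-fold (3.94 to 4.48) higher, the pluripotency factor UTF1 3.53-fold higher, NANOG 2.92-fold higher and L1TD1 1.66-fold higher. The 18 measured pluripotency genes had a median of 0.81 (random lists -0.26 to 0.23). The pluripotency list held 0.229% of UMIs in cluster 12, with 9.35% of day 12 cells. It held 0.0638% in cluster 2, with 77.1% of day 12 cells, and 0.0710% in the day 8 library. UTF1 was among the leading genes of cluster 12, which helped to define it. LIN28A was found in 8.79% and L1TD1 in 68.1% of thinned day 12 cells. The embryonic gene ARGFX was 2.64-fold lower and KLF5 1.66-fold lower. ID3 was 8.87-fold higher and ID1 3.10-fold higher, the growth factor BMP4 was 5.48-fold higher, and the BMP target list had a median of 1.60 (random lists -0.48 to 0.32). ISLR, a stromal cell surface gene, was 27.2-fold (24.0 to 30.9) higher and the adhesion molecule CEACAM1 11-fold higher. MIR205HG, host of the epithelial miR-205, was 6.01-fold higher, and the lipid carrier APOE 5.48-fold higher. Matrix genes at higher level included LUM (6.38-fold), the collagen COL3A1 (4.20-fold), matrix Gla protein MGP (6.07-fold), the microfibril gene MFAP4 (4.97-fold) and CCDC80 (4.67-fold). In the fibroblast list 9 of 25 members were at least 2-fold higher, 2 lower, and the median was 0.62 (random lists -0.31 to 0.06). The list's lower members were lysyl oxidase (LOX), 4.51-fold lower, and thrombospondin THBS1, 4.66-fold lower. JARID2, a polycomb partner, was 2.05-fold higher and another one, PHF19, 2.06-fold lower.

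The YAP targets CCN2 and CCN1 were 6.90-fold (6.60 to 7.21) and 5.23-fold lower, the TGF-beta family ligand INHBA 2.95-fold lower, and the list of such targets had a median of -0.48 (random lists -0.30 to 0.22). ACTG2 was 8.47-fold (8.02 to 8.96) lower and MYL9, a myosin light chain, 2.17-fold lower. CAV1 was 3.72-fold lower. The TWEAK receptor TNFRSF12A, the vasoactive peptide ADM and the progenitor marker CD34 were 3.74-fold, 4.20-fold and 4.0-fold lower. Secreted factors IGFBP3 and IL1B were 2.92-fold and 2.42-fold lower. The glycolytic enzyme LDHA was 2.12-fold lower. The G2 and M phase list had a median of -0.34 (random lists -0.23 to 0.035), with JPT1 2.01-fold lower, the mitotic ubiquitin enzyme UBE2C 1.80-fold lower and CKS1B 1.83-fold lower. The 37 measured S phase genes had a median of -0.29 (random lists -0.21 to 0.11), with the checkpoint adaptor CLSPN 1.89-fold lower. The keratinocyte, trophoblast and neural lists stayed inside the range of random lists, at medians of -0.29, -0.15 and 0.22.

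The TRA-1-60 positive against the negative library at day 16 asked which transcripts parted the cells that carried the epitope from those that did not. The positive library had far more of the pluripotency transcripts, more epithelial junction transcripts and more of the transcripts of proliferating cells. The negative library had more matrix, secreted and keratinocyte transcripts, and more of the cell cycle inhibitors CDKN2A and CDKN2B. Its share of mesenchymal surface transcripts was only slightly larger, although some genes of that list were far higher in it. Transcripts of PODXL itself differed little, 1.26-fold higher in the positive library. By the rule of size 621 genes were higher and 690 lower in the positive library, of 4536.

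POU5F1 was 100.5-fold (95 to 106) higher in the positive library, LIN28A 123-fold (104 to 146) higher and NANOG 11.6-fold (11 to 12.2) higher, while SOX2 was 4.21-fold higher and KLF4 4.48-fold higher. MYC was at 34.2 CPM in the positive and 33.0 CPM in the negative library. Of 21 pluripotency genes at level 20 were at least 2-fold higher and none lower, with a median over 28 measured genes of 3.77 (random lists -0.47 to 0.37). DPPA2 and DPPA4, developmental pluripotency genes, were 580.1-fold and 131-fold higher, the transcription factor ZSCAN10 239-fold higher and the growth factor NODAL 168-fold higher. DPPA2 and ZSCAN10 had only 8 and 13 UMIs in the negative library, so their folds are rough. FOXH1, the transcription factor that serves Nodal signals, was 111-fold higher, and the de novo DNA methyltransferase DNMT3B 90.8-fold higher. LINC01356, LINC02617 and FOXD3-AS1, long noncoding transcripts, were 744-fold, 135-fold and 105-fold higher. NLRP7, a gene of oocytes and early embryos, was 102-fold higher, skeletal actin ACTA1 113-fold higher, the neuropeptide NTS 69.3-fold higher and MT1H 59.4-fold higher. In the epithelial list the splicing regulator ESRP1 was 25-fold higher, the adhesion molecule EPCAM 18.8-fold higher, claudin CLDN6 16.0-fold higher and the polarity gene CRB3 9.47-fold higher, with a median of 2.06 (random lists -0.45 to 0.39). TET1, JARID2 and DNMT3A, enzymes and partners of DNA methylation and polycomb, were 9.75-fold, 8.32-fold and 6.05-fold higher.

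Proliferation genes were higher in the positive library. The chromatin helicase HELLS was 14.5-fold (14.0 to 15.2) higher, CENPU 9.23-fold higher and the replication licensing factor CDC6 8.01-fold higher, and 20 of 24 S phase genes were at least 2-fold higher, with a median of 1.85 (random lists -0.38 to 0.27). In the G2 and M phase list 28 of 35 genes were at least 2-fold higher and none lower, with a median of 2.11 (random lists -0.29 to 0.23); DLGAP5 was 9.65-fold higher, UBE2C 8.54-fold higher and the mitotic kinase AURKB 7.48-fold higher. The chromatin assembly genes CHAF1A and NASP were 5.64-fold and 4.21-fold higher. The glucose transporter SLC2A3 was 4.34-fold higher and LDHA 2.23-fold lower. Interferon-induced IFITM1 was 5.80-fold higher, whereas IFI6 and IFI27 were 7.30-fold and 4.88-fold lower.

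Lower in the positive library were CDKN2A, by 17.2-fold (16.3 to 18.1), and CDKN2B, by 8.81-fold (8.00 to 9.73); these encode the p16 and p15 inhibitors of the cell cycle. The p53 target GDF15 was 4.97-fold lower and FAS 4.35-fold lower. Within the fibroblast list 21 of 25 members were at least 2-fold lower and 1 higher, the growth factor receptor PDGFRA; COL6A3 was 27.9-fold (25.8 to 30.2) lower, LUM 26.3-fold lower, PDGFRB 20.2-fold lower and the mesenchymal homeobox gene PRRX1 19.9-fold lower. The list median was -2.95 (random lists -0.28 to 0.35). Elastin (ELN) and matrix Gla protein (MGP) were 30.9-fold and 63.9-fold lower. The surface enzyme NT5E was 17.4-fold lower and endoglin (ENG) 11.8-fold lower. The mesenchymal surface list as a whole held 0.122% of UMIs in the positive and 0.151% in the negative library. For the secreted list these shares were 0.0385% and 0.340%, and for the keratinocyte list 0.0127% and 0.0396%. A share of UMIs rests mostly on abundant members. Of the surface list, ANPEP, CD44 and PROCR were found in 1.63%, 30.9% and 12.7% of thinned positive cells. In thinned negative cells they were found in 19.7%, 75.4% and 31.1%. INHBA, LTBP2 and TGFBR2 of the TGF-beta list were 13.5-fold, 19.8-fold and 5.76-fold lower, and the list median was -1.70 (random lists -0.59 to 0.50). Chemokines CXCL1 and CCL2 were 13.2-fold and 6.74-fold lower and IGFBP5 10.3-fold lower. The stratified epithelium genes S100A7, SPRR3, KRT6A, KRT16 and S100A2 were 75.1-fold, 49.6-fold, 16.4-fold, 10.7-fold and 12.5-fold lower. Most UMIs of S100A7 and SPRR3 came from 1 small cluster, number 11, with 5.19% of negative and 1.05% of positive cells, which held 96.2% and 73.3% of their UMIs in the negative library; outside it S100A7 was at 2.52 CPM in the negative and 0.126 CPM in the positive library, and SPRR3 at 36.0 and 0.995 CPM. JUNB was 15.3-fold lower, HAND1 14.2-fold lower and STMN2, a neuronal microtubule regulator, 14.7-fold lower. The 10% of genes with the highest transcript GC content had a median log2 ratio of -0.39, against -0.04 to 0.23 in the other 10% steps.

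**Figure D2:**
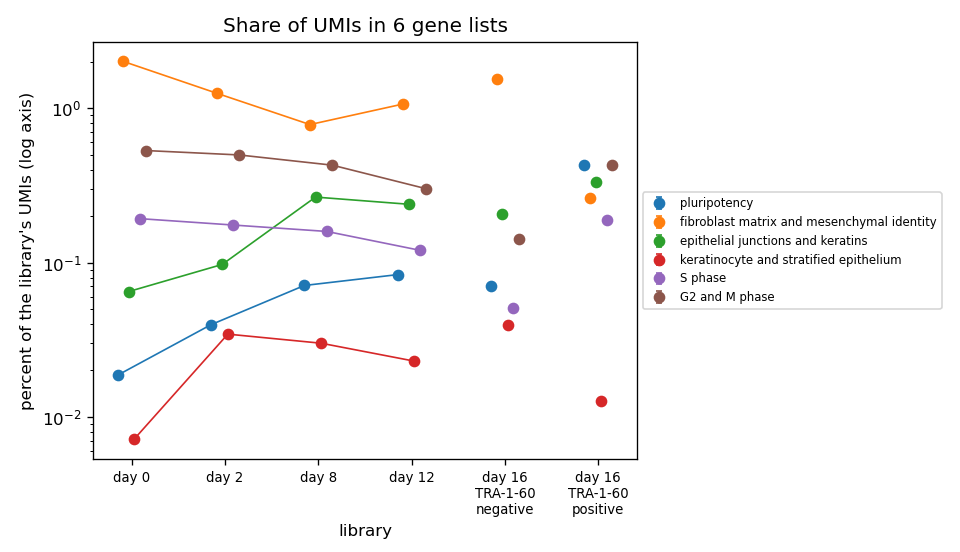
Share of each library's UMIs in selected gene lists, in percent on a log axis, with bars, mostly smaller than the points, for the exact 95% interval and lines joining days 0 to 12 only. The pluripotency list holds 0.426% of UMIs in the TRA-1-60 positive library and 0.0708% in the negative library, where CD9, which day 0 cells also express, has 316 CPM of it.

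The TRA-1-60 positive library against day 0 asked how far the sorted reprogramming cells stood from the starting fibroblasts. Pluripotency and epithelial transcripts that day 0 lacked were abundant. Most genes of the fibroblast, mesenchymal surface and contractile lists were lower. The S phase list was close to its day 0 level, and the G2 and M phase list slightly lower. By the same rule 601 genes were higher and 1326 lower of 4922, and 1248 and 1250 when ribosomal protein and mitochondrial UMIs were left out of the total. Ribosomal protein genes made up 22.5% of UMIs at day 0 and 34.4% in the positive library.

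POU5F1 reached 1065 CPM from 3 UMIs at day 0. TDGF1 was at least 34915-fold higher, the Nodal antagonist LEFTY2 at least 19536-fold higher, the TGF-beta family ligand GDF3 at least 13272-fold higher, NODAL at least 9262-fold higher and LIN28A at least 6790.5-fold higher. DPPA4 reached 169.7 CPM from 2 UMIs, and the pluripotency transcript LINC00678 129 CPM from 1 UMI. NANOG was 1894-fold (1058 to 3795) higher, SOX2 at least 787-fold higher and KLF4 11.5-fold (9.73 to 13.7) higher. All 21 pluripotency genes at level were at least 2-fold higher, with a median over 28 genes of 5.13 (random lists -0.66 to 0.51), or 10.13 with members at 0 set to the floor. E-cadherin (CDH1) was at least 1529-fold higher, ESRP1 at least 1221-fold higher and CLDN6 4338-fold higher, and the vesicle trafficking gene RAB25 reached 45.9 CPM from 1 UMI. The epithelial list had a median of 4.41 (random lists -0.83 to 0.72), or 6.99 with members at the floor. MIR205HG, HPGD, the secretoglobin SCGB3A2 and NTS were at least 18148-fold, at least 12107-fold, at least 11345-fold and at least 9818-fold higher. JARID2 and TET1 were 38.2-fold and 15.3-fold higher, and DNMT3A 8.86-fold higher. The glucose transporter SLC2A3 was 14.7-fold higher and the immediate early gene FOS 12.3-fold higher. Oxidative phosphorylation genes had a median of 0.49 (random lists -0.35 to 0.40), or 0.39 and inside the random range with the trend over GC content removed, with COX7C 3.12-fold and UQCRH 2.86-fold higher, but CYC1 7.94-fold lower.

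Lower genes were led by FGF5, a growth factor, at 495-fold (333 to 773) lower, the pregnancy-specific glycoprotein gene PSG4 at 431-fold, the WNT antagonist DKK1 at 344-fold and OXTR at 304-fold. In the fibroblast list 26 of 28 members were at least 2-fold lower and none higher, with a median of -3.03 (random lists -0.48 to 0.29); THBS1 was 102-fold lower, LOX 63.0-fold lower, PRRX1 48.9-fold lower and COL6A3 37.2-fold lower. The surface genes ANPEP, CAV1, ENG and NT5E were 50.3-fold, 39.7-fold, 18.3-fold and 9.71-fold lower, and 8 of 9 genes of their list were at least 2-fold lower, with a median of -2.63 (random lists -0.84 to 0.54). ACTA2 and TPM2 were 10.4-fold and 9.49-fold lower, as were 7 of 9 contractile genes by at least 2-fold, with a median of -2.06 (random lists -0.78 to 0.54). The YAP targets CCN1 and CCN2 were 45.6-fold and 18.6-fold lower, and the TGF-beta and YAP target list had a median of -2.94 (random lists -0.84 to 0.46). ID1 and ID3 were 20.5-fold and 6.42-fold lower. The secreted factors MMP3, IGFBP3 and IL11 were 145-fold, 86.6-fold and 86.9-fold lower. DUSP1, FOSL2 and JUN were 69.1-fold, 14.0-fold and 13.5-fold lower. KRT7, a keratin in the trophoblast list, was 135-fold lower. The S phase list had a median of 0.01 (random lists -0.50 to 0.17) and the G2 and M phase list one of -0.45 (random lists -0.43 to 0.14); within them HELLS was 4.99-fold higher, while thymidylate synthase (TYMS), SLBP, MKI67 and the centromere histone CENPA were 5.27-fold, 7.90-fold, 5.92-fold and 7.19-fold lower. The endoderm list held 0.000983% (0.000921 to 0.00105%) of UMIs, against 0.000164% (0.000143 to 0.000187%) at day 0, and the leukocyte list 0.000986% (0.000924 to 0.00105%) against 0.00241% (0.00233 to 0.00249%). The primitive streak and mesoderm list held 0.00486% (0.00472 to 0.00500%) against 0.00211% (0.00203 to 0.00219%) at day 0. That list includes PDGFRA, which is also in the fibroblast list and had at least 25 CPM in the positive library. Its share is therefore not one of primitive streak genes alone.

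Part of the lower set was shared by both day 16 libraries. Of 2324 genes within 2-fold over days 0 to 12, 131 were at least 2-fold lower in both day 16 libraries than in the lowest of the 4 earlier ones, and none were higher. For the other 14 pairs of libraries the same count of lower genes was between 0 and 17. The transcription and translation factor YBX1 was at 1682, 2423, 2078 and 1751 CPM at days 0 to 12, and at 309 and 290.3 CPM in the negative and positive libraries. The ATP synthase subunit ATP5F1D, at 444 CPM at day 12, was at 35.8 and 17.0 CPM; both genes were chosen after their values were seen. CENPA, CYC1, PHLDA3 and TYMS of the named genes belonged to this set, and MKI67 and SLBP, which were not steady before, were also at least 2-fold lower in both. Its median transcript GC content was 56.0%, against 48.0% in the other steady genes. Among all genes the 10% with the highest GC content had a median log2 ratio of -0.99 in the positive library against day 0, and the other 10% steps -0.35 to -0.06. The day of sampling and the handling of the day 16 libraries cannot be told apart here.

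The TRA-1-60 negative library against day 0 asked where the cells without the epitope stood at day 16. Most fibroblast matrix transcripts were within 2-fold of day 0, and the transcripts of proliferating cells were lower. The cell cycle inhibitors CDKN2A and CDKN2B, the keratins KRT6A, KRT16 and KRT8 and cornified-envelope transcripts were higher, and so was a limited set of pluripotency transcripts. Under that rule 421 genes were higher and 1082 lower of 4805, and 862 and 977 when ribosomal protein and mitochondrial UMIs were left out of the total. The median cell had 5.37% mitochondrial UMIs, against 2.55% at day 0.

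CDKN2A was 7.33-fold (7.12 to 7.55) higher and CDKN2B 24.1-fold (21.1 to 27.6) higher. GDF15 and the p53-induced ribonucleotide reductase RRM2B were 8.12-fold and 5.23-fold higher, and 8 of 15 genes of the p53 target and inhibitor list were at least 2-fold higher, with a median of 1.15 (random lists -0.59 to 0.21). Filaggrin (FLG) and SPRR3, genes of the cornified layer of skin, were at least 7522-fold and at least 5784-fold higher, KRT6A at least 6407-fold higher and KRT16 836-fold higher, and S100A7 reached 62.4 CPM from 1 UMI. Cells of cluster 11, 5.19% of the negative library, held 96.2% of the S100A7 UMIs there, 73.3% of SPRR3, 43.9% of KRT16, 41.3% of FLG and 30.3% of KRT6A. The simple-epithelium genes KRT8, SPINT2 and claudin CLDN4 were 17.9-fold, 146-fold and 385-fold higher, with an epithelial list median of 2.74 (random lists -0.75 to 1.36), or 4.08 with members at the floor. LEFTY2 was at least 4504-fold higher, L1TD1 63.3-fold higher, NANOG 163-fold higher and PODXL 35.8-fold higher. Clusters with fewer positive than negative cells held 93.1% of the negative cells. Of the negative library's UMIs they held 31.3% for LEFTY2, 72.7% for NANOG and 84.1% for L1TD1. POU5F1 was at 10.6 CPM against 3 UMIs at day 0. CD70 reached 215 CPM from 2 UMIs, HPGD was at least 10148-fold higher, the ribonuclease RNASE1 at least 8904-fold higher, and calbindin (CALB1) at least 4932-fold higher. HAND1 was at least 2055-fold higher. The angiopoietin receptor TEK was 31.1-fold higher, S100A4, a calcium-binding protein in the fibroblast list, 3.47-fold higher, and the glucose transporters SLC2A3 and SLC2A1 3.38-fold and 3.34-fold higher. Oxidative phosphorylation genes had a median of 0.43 (random lists -0.48 to 0.23), with COX7C 2.49-fold higher and CYC1 3.85-fold lower.

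Proliferation genes were lower than at day 0. In the G2 and M phase list 41 of 43 genes were at least 2-fold lower, with a median of -2.45 (random lists -0.38 to 0.08); PIMREG was 21.3-fold lower, the proliferation marker MKI67 17.4-fold (16.3 to 18.7) lower and the kinetochore-linked CDCA8 12.4-fold lower. In the S phase list 19 of 24 were at least 2-fold lower, with a median of -1.98 (random lists -0.40 to 0.17), RRM2 being 17.5-fold lower and ATAD2 10.8-fold lower. The histone chaperones ASF1B and CHAF1A were 9.03-fold and 6.45-fold lower, the maintenance methyltransferase DNMT1 3.26-fold lower and EZH2, the polycomb methyltransferase, 4.45-fold lower. CENPA, TYMS, IER2 and CYC1 belonged to the genes lower in both day 16 libraries, 28.6-fold, 11-fold, 3.34-fold and 3.85-fold lower here, and MKI67 and IGFBP7 were also at least 2-fold lower in both. The 10% of genes with the highest GC content had a median log2 ratio of -0.59, and the other 10% steps -0.39 to -0.20. The fibroblast list had a median of -0.61 (random lists -0.48 to 0.13), with 7 of 27 members at least 2-fold lower and 1 higher; FN1, LOX and THBS1 were 3.74-fold, 5.66-fold and 6.80-fold lower. CAV1 was 8.95-fold lower and the keratin KRT7 29.5-fold lower. The contractile genes CNN1, TPM1 and TAGLN were 12.2-fold, 5.12-fold and 4.14-fold lower, with a list median of -1.63 (random lists -0.72 to 0.41). ID4, ID3, ID2 and ID1 were 41.3-fold, 13.5-fold, 9.87-fold and 6.39-fold lower. The secreted factors MMP3, IGFBP3 and IGFBP7 were 32.7-fold, 17.6-fold and 9.70-fold lower. HES4, a Notch-pathway repressor, was 178-fold lower, the chemokine CXCL12 71.2-fold lower, the BMP antagonist GREM1 39.5-fold lower and FGF5 63.7-fold lower. DUSP1 was 29.3-fold lower.

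Shares of cells with at least 1 UMI asked whether these levels came from few or many cells. They were taken in cells thinned to 11000 UMIs, a step that left out 207 cells at day 0, 210 at day 2, 100 at day 8, 1258 at day 12, 1176 in the negative and 21 in the positive library. The exact 95% interval of these shares reached at most 1.93 percentage points to either side. POU5F1 was found in 0.0291% of day 0 cells, the background, and in 6.40%, 6.02%, 12.1%, 3.76% and 79.6% of cells in the later libraries. Unthinned, these shares were 0.0424%, 12.4%, 13.7%, 15%, 5.29% and 90.5%, at median depths from 15714 to 33562 UMIs. NANOG was found in 0.0728% of day 0 cells, in 12.2% at day 12, in 11.6% of negative and 69.5% of positive cells; unthinned, the shares were 0.155%, 15.5%, 16.4% and 86.9%. LIN28A was found in 0 cells at day 0, which allows a share of cells with a UMI of up to 0.0437% by a limit of 3 counts, in 8.79% at day 12 (10.0% unthinned) and in 61.2% of positive cells (76.6% unthinned). L1TD1 was found in 2.20% of day 0, 50.7% of day 8, 57.1% of negative and 79.8% of positive cells, and unthinned in 3.62%, 65.8%, 62.4% and 86.9%. The collagen COL1A1 was found in 55.5% of day 8 cells, 90.9% of negative and 26.8% of positive cells, and unthinned in 72.2%, 94.2% and 44.2%. The positive library was chosen in advance as background for fibroblast genes, but it is not free of cells that express them. Of its cells 5.23% lay in cluster 1, with 82.2% of the negative cells. LUM was found in 57.9% of day 0, 6.39% of day 8, 40.3% of negative and 1.71% of positive cells, and unthinned in 70.2%, 11.7%, 46.1% and 3.12%. KRT7 was found in 58.7% of day 0 and 1.21% of positive cells (66.0% and 3.84% unthinned).

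The number of detected pluripotency genes per thinned cell gave a graded picture. At least 3 of 33 such genes were found in 7.57% of day 0 cells, the background, and in 26.5%, 63.5%, 67.6%, 52.8% and 98.2% of the cells at day 2, at day 8, at day 12 and in the negative and positive libraries. Day 0 cells express 6 of these genes at 1 CPM or more, CD9 and TERF1 most; with the other 27 alone, a choice made after seeing the data, the shares were 0% at days 0 and 2, 8.95% at day 8, 15.4% at day 12, 5.37% in the negative and 91.3% in the positive library. The class is a range, since 39.0%, 57.2%, 46.5%, 47.1%, 55.7% and 3.22% of cells had 2 or 3 such genes. At least 8 were found in 1.96% of cells at day 8, 7.89% at day 12, 1.18% in the negative and 80.5% in the positive library, and in none at day 0 or day 2. Within day 8 the median number of fibroblast list UMIs per cell was 105 in cells with 1 or 2 detected pluripotency genes and 46 in cells with 6 or more, while the epithelial list had 16 and 31 and the G2 and M phase list 31 and 37, with means of 44.7 and 44.8. Within day 12 the fibroblast medians were 140 and 37, and the G2 and M phase list had 12 and 32, with means of 25.9 and 38.1. Within the negative library the fibroblast medians were 173 and 71, in 2485 and 253 cells, and within the positive library 134 and 21, in 45 and 2349 cells.

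**Figure D3:**
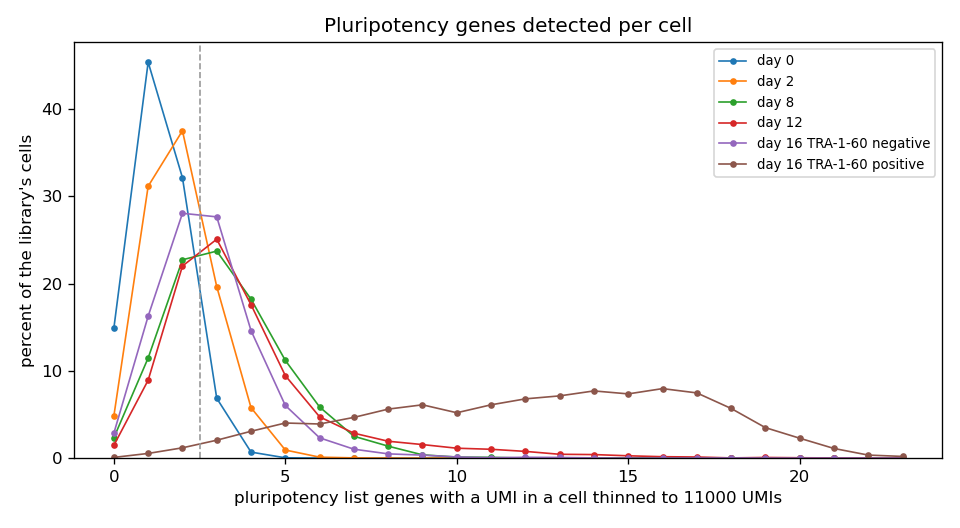
Distribution over cells of the number of pluripotency genes with a UMI, in percent of the cells thinned to 11000 UMIs, for each library, with a dashed line at the limit of 3 genes. The median cell of the TRA-1-60 positive library had 13 such genes, and that of the negative library 3.

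Clusters asked which cells of the libraries resembled each other. Leiden clustering of all cells gave 15 clusters, most of them made of 1 library, and such a cluster may be that library and not a cell type. At day 0 the clusters 3, 6 and 9 held 56.3%, 26.8% and 16.8% of cells, and the exact 95% interval of the cluster shares reached at most 1.92 points to either side. Cluster 4 held 76.8% of day 2 cells, cluster 5 80.5% of day 8 cells and cluster 2 77.1% of day 12 cells. The negative library lay mostly in cluster 1, with 82.2% of its cells against 5.23% of the positive cells. The positive library was split between cluster 8, with 54.0% of its cells, and cluster 7, with 39.1%; cluster 7 also held 6.70% of the negative cells. Cluster 12 held 9.35% of day 12 cells.

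**Figure D4:**
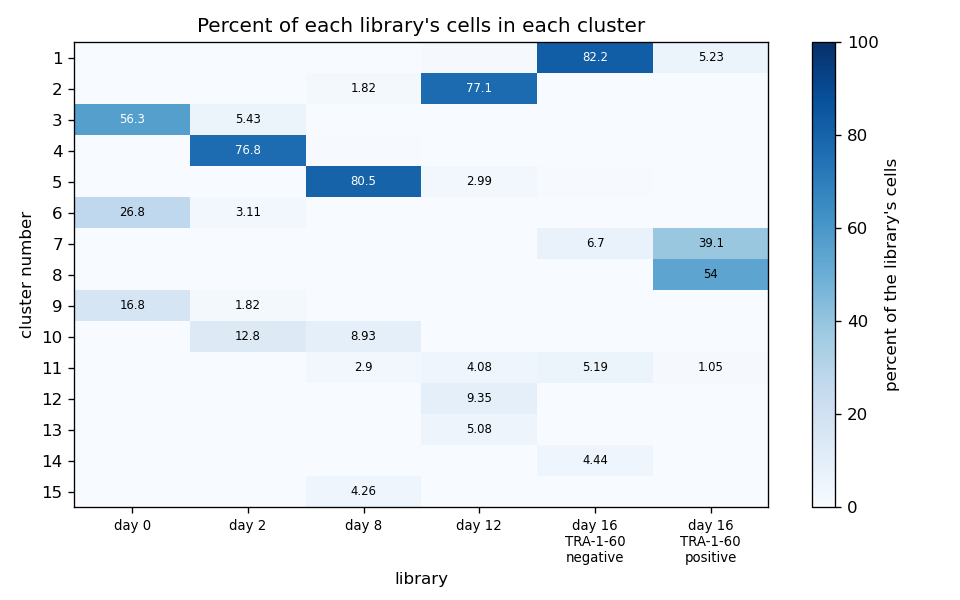
Share of each library's cells in each Leiden cluster, in percent, with the library on the horizontal and the cluster on the vertical axis and shares of at least 1% printed. Cluster 8 holds 54.0% of the TRA-1-60 positive cells.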

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

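Of the tests in this part, those on the GC content trend and on the genes lower in both day 16 libraries were chosen only after the result was seen.

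Some named genes were higher than at day 0 in 1 TRA-1-60 fraction of day 16 and lower in the other, both being compared with the same day 0 library. Cell cycle inhibitor CDKN2A was at 37.2 CPM at day 0, 273 CPM in the negative and 15.9 CPM in the positive library, a difference between the log2 ratios, positive minus negative, of -4.10. The DNA methylation cofactor HELLS went the other way, at 62.3, 21.4 and 311 CPM, a difference of 3.86. Lower in the positive and higher in the negative library than at day 0 were also the chloride channel gene CLIC3, with a difference of -5.51, the calcium-binding S100A4 and S100A2, with -3.92 and -3.65, and the AP-1 subunit JUNB, with -3.94. STMN2, which encodes a neuronal microtubule regulator, differed by -3.88, the secreted IGFBP5 and CCL2 by -3.37 and -2.75, and the receptor TGFBR2 by -2.53. These differences were not tested, since each group was 1 library, and no biological explanation of them was tested either.

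The lower cell cycle transcripts of the TRA-1-60 negative library against day 0 were weighed further, since HELLS and CDKN2A both bear on the cell cycle. The G2 and M phase list had a median log2 ratio of -2.45. Cells with under 1000 genes or over 10% mitochondrial UMIs were too few to be the cause. With the other 6177 of 6781 negative cells the median was -2.40, and leaving out so few cells could hardly have changed it. Low quality among the kept cells was not tested. Fewer UMIs per cell are argued against by the median of -2.29 in cells of 15000 to 22000 UMIs, where all 54 members were lower. The trend with GC content was too small to give a median of -2.45, as its 10% steps ran from -0.59 to -0.20. Its removal, which left -2.45, could not have come out otherwise and adds nothing. Only 2 of 53 members were at least 2-fold lower in both day 16 libraries. This argues against a shared loss of transcripts as the whole cause. For those 2, CENPA and MKI67, a shared loss of transcripts and a change in the negative cells cannot be told apart, as they were picked by being lower in both. No biological explanation was tested, and a difference in the handling of single libraries stays open.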

How the results depend on the processing

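No paired analysis was possible because each group was 1 library. The totals without ribosomal protein and mitochondrial UMIs, the cells without the highest 6% of doublet scores, the removal of the GC content trend, the restriction to pluripotency genes under 1 CPM at day 0 and the omission of the genes lower in both day 16 libraries were added after seeing the data. All 12 counts of genes stayed within 1.5 times the main count under TMM factors, median-of-ratios factors, filtered cells, the mean over cells of each cell's CPM, both omissions of doublets, removal of the GC content trend and omission of the day 16 genes. Without ribosomal protein and mitochondrial UMIs the higher genes numbered 320, 374, 272, 1248 and 862 in the comparisons day 2 with day 0, day 8 with day 2, day 12 with day 8, and the positive and negative libraries with day 0. In the order of the report, with at least 10 UMIs as the sole minimum, 2500, 2953, 2252, 3628, 5193 and 4763 genes were higher and 1122, 1691, 1037, 4464, 4232 and 3061 lower. At a minimum of 100 CPM 53, 75, 31, 189, 189 and 116 were higher and 90, 80, 49, 181, 497 and 425 lower. At a ratio of 1.5 490, 467, 344, 1203, 1024 and 750 were higher and 583, 940, 634, 1080, 1816 and 1700 lower. A different minimum or ratio by construction counts a different number of genes.

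The median of all genes moved by over 0.1 log2 in these cases: by -0.12 under TMM and -0.15 under median-of-ratios factors for day 2 against day 0, and under the latter by 0.12 for the positive against the negative library and -0.12 for the negative against day 0. Without ribosomal protein and mitochondrial UMIs it moved by 0.13, 0.21, 0.38 and 0.34 for day 2 against day 0, day 12 against day 8, and the positive and negative libraries against day 0.

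Among 654 values of named genes, none of those at least 2-fold apart reversed under any alternative run on them. Smaller ratios were not judged for reversal. At most 11 crossed below the 2-fold ratio in 1 setting, the removal of the GC content trend. Of 144 list medians, only those outside the range of random lists were judged for reversal. Of these, 3 reversed when all members with any UMI were used. Naive pluripotency at day 12 against day 8 went to 0.22. Neural genes in the positive against the negative library went to 0.032, and trophoblast and amnion genes in the positive library against day 0 to 0.12. Other settings took at most 9 medians outside the range of random lists and at most 5 into it. The use of all members took 9 further medians outside the range of random lists and 2 into it. Among medians printed in the report, that of the pluripotency list for day 2 against day 0 was 0.02 over all members, and that of the oxidative phosphorylation list for the positive library against day 0 was 0.39 with the GC content trend removed, inside the range of random lists. The cause was not tested.

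In cells with at least 1000 genes and at most 10% mitochondrial UMIs the pluripotency list held 0.0735% of UMIs in the negative library, and the fibroblast list 2.01%, 1.25%, 1.06%, 1.56% and 0.259% at days 0, 2 and 12 and in the negative and positive libraries, each outside the narrow counting interval. Shares of cells with a UMI moved outside their interval for 117 of 132 values without thinning, 113 at the lower depth and 123 with at least 2 UMIs required, which ask for more or less by construction. The share of cells with pluripotency genes, by library in order of time, was 39.7, 64.0, 86.2, 89.6, 80.9 and 99.4% for 2 or more genes, 0.0291, 1.05, 21.5, 24.9, 10.5 and 93.1% for 5 or more, and 21.2, 56.8, 87.2, 75.3, 64.3 and 99.5% for 3 or more without thinning. With only the members under 1 CPM at day 0 it was 0% at days 0 and 2, 8.95% at day 8, 15.4% at day 12, 5.37% in the negative and 91.3% in the positive library, as fewer genes could count. Clusters depended on their settings. Resolution 1.0 gave 23 clusters, the largest holding 29.4, 41.8, 42.1, 46.7 and 59.4% of the cells at days 0, 2, 8 and 12 and of the negative library. At resolution 0.25 the largest held 73.2, 89.5, 84.8, 89.3, 86.6 and 89.8%. With 4000 variable genes it held 74.9, 84.2, 74.7, 85.4 and 48.1% at days 0, 8 and 12 and in the negative and positive libraries, and without S and G2 and M phase genes 71.5, 70.4, 86.1 and 46.9% at days 0 and 12 and in the negative and positive libraries. Depth limits genes below about 1 CPM, where a ratio rests on few UMIs, and the thinned cells miss transcripts present in low number.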

Other observations

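All tests in this part except that on cells with a SOX2 or POU5F1 UMI, and the comparisons with day 12, were chosen only after the result was seen.

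Against day 12, the last unsorted library, the TRA-1-60 positive library had higher transcripts of most pluripotency genes, though UTF1, at under 25 CPM, was lower. NODAL was 68.4-fold higher, its antagonists LEFTY2 and LEFTY1 were 44.0-fold and 35.1-fold higher, and FOXH1, which serves Nodal signals, was 22.3-fold higher. POU5F1, NANOG and LIN28A were 25.2-fold, 8.61-fold and 7.93-fold higher, DPPA4 32.9-fold higher and CLDN6 11.3-fold higher. The striated muscle actins ACTA1 and ACTC1 were 80.9-fold and 33.0-fold higher. The median of the pluripotency list was 3.06 (random lists -0.37 to 0.42). MGP, COL3A1, COL6A3 and PDGFRB were 35.9-fold, 18.4-fold, 14.4-fold and 17.5-fold lower, with a fibroblast list median of -2.07 (random lists -0.28 to 0.40), and HAND1 and CDKN2A were 25.6-fold and 9.88-fold lower. By the rule of size 521 genes were higher and 861 lower of 4625.

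The TRA-1-60 negative library had more matrix and TGF-beta-responsive transcripts than day 12. The fibroblast list held 1.55% of UMIs in the negative library, against 1.07% at day 12. FN1 was 5.89-fold higher, COL1A1 3.05-fold higher, ELN 5.66-fold higher and INHBA 5.54-fold higher, and CCN2 was 4.08-fold higher. PMEPA1, a TGF-beta-induced gene, was 6.71-fold higher, the chemokine CXCL14 22.2-fold higher and the prostaglandin synthase PTGDS 8.10-fold higher. The list of TGF-beta and YAP targets had a median of 0.83 (random lists -0.35 to 0.32) and the contractile list one of 1.19 (random lists -0.34 to 0.41). LIN28A and POU5F1 were 15.5-fold and 3.98-fold lower. UTF1 was 169.7-fold lower. It was also lower than at day 12 in the positive library, at under 25 CPM, so the direction was not particular to the negative cells. How far it differed between the fractions is not given here. LEFTY2 was 10.1-fold higher, though clusters with fewer positive than negative cells, 93.1% of the negative cells, held only 31.3% of its UMIs there. TOP2A and MKI67, genes of dividing cells, were 7.23-fold and 7.15-fold lower. By size 174 genes were higher and 476 lower of 4392. C4orf48, H1-10 and CENPA, which belonged to the set lower in both day 16 libraries, were 42.9-fold, 30.3-fold and 24.2-fold lower.

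A small cluster, number 11, gathered cells mostly of 4 libraries with transcripts of the cornified layer of skin, namely SPRR1A, S100A7, CSTA and CDSN. It held 2.90% of day 8 cells, 4.08% of day 12 cells, 5.19% of negative and 1.05% of positive cells. In cluster 12, within day 12, the leading genes were UTF1, APOE, MIR205HG, TRIML2 and EPCAM. Those of cluster 7, which held cells of both day 16 fractions, were NTS, COL2A1, LEFTY2 and SFRP2, and those of cluster 8 were DPPA2, DPPA4, LINC01356 and DNMT3B. These genes helped to define the clusters.

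Alpha-globin transcripts at day 2 came to 136904 UMIs of HBA1 and HBA2. Of 14 erythroid markers, erythroid cells or their RNA would bring all; they gave UMIs equal to 10.2% of the HBA1 and HBA2 UMIs, but 98.8% of these came from SLC25A37 and BLVRB, which day 0 cells also express, so that test decided nothing. The 12 markers under 1 CPM at day 0, among them HBB and ALAS2, gave 0.126%, which argues against erythroid cells as the whole cause. HBB stood at 1.07 CPM, HBE1 had 15 UMIs and ALAS2 none, whereas HBZ, an embryonic globin of the alpha gene cluster that was not among the markers, had 21686 UMIs; the labels name no sort of the day 2 cells. Free RNA spread evenly over the droplets is argued against by the 30.3% of thinned cells with no HBA1 or HBA2 UMI, where a Poisson spread would leave 0.00160%. Transcription in the cells that carry the reprogramming factors may be the source. The mean was 1.34 times as high in cells with a SOX2 or POU5F1 UMI (14.1 against 10.5), between the bounds of 1.2 and 1.5 set in advance. Some of the 4051 cells without such a UMI may carry the factors undetected. SOX2 was found in 10.1% of thinned and 20.3% of unthinned day 2 cells. Missed detection would make the ratio smaller, so it could not decide the question, and this source stays open.

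Pluripotency transcripts in the TRA-1-60 negative library were weighed against carry-over of positive cells. POU5F1 there stood at 0.995% of its level in the positive library. TRA-1-60 positive cells or their RNA carried over would bring every member at that fraction, but 15 of 21 members were over 2 times it, such as L1TD1 at 35.7%, LEFTY2 at 23.1% and NANOG at 8.61%, and so were 9 of the 15 under 1 CPM at day 0, which argues against an even carry-over as the whole cause. For the other 6 members, LIN28A, DPPA2, DPPA4, DNMT3B, NODAL and ZSCAN10, carry-over and low expression cannot be told apart, since they were picked by that fraction. Carry-over of cells like those of cluster 7 of the positive library stays open; 454 negative cells, 6.70%, lay in that cluster. Against the level in its positive cells 11 members were over 2 times the POU5F1 fraction, but 6 of these had 1 CPM or more at day 0, and of the 15 low at day 0 only 5 were, among them LEFTY2, whose ratio to POU5F1 was 3.10 times that of those cells. In clusters with fewer positive than negative cells, 5 of those 15 had over 50% of their negative-library UMIs, which leaves it open for the set; L1TD1, at 2.1 CPM at day 0 and 133 CPM in the negative library, had 84.1% of them there, which argues against such cells as its main source. No biological explanation was tested.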
